A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

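RNA was measured in 8 yeast libraries, 2 each from wild type and RAD27 knockout cells kept for 4 hours at 30 or 37 °C after dilution of an overnight culture. The deposited values are raw read counts per gene, for which the authors' processing notes name STAR for alignment, HTSeq for counting and the builds R64 and sacCer3. Versions, strand use and the handling of reads that map to several places are not given in the sources used here. Genome sequencing that the series description mentions was not used here. The deposited counts are whole numbers for 6692 genes, with 224 at 0 in all libraries. Systematic names matched an R64 annotation for 6008 genes, and the other 684 held 0.164% of counts. Library totals lay between 4734266 and 5588983, so that 3 counts in a library correspond to 0.537 to 0.634 CPM before TMM scaling.

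Counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, current form of the method) on all 8 libraries with 1 coefficient per group and no block. Scaling was by TMM, and filterByExpr by group with a minimum count of 10 and a minimum total of 15 left 5667 genes. The p was adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. The 5 comparisons were 37 against 30 °C in each genotype, knockout against wild type at each temperature, and the difference between the temperature responses of the genotypes, called the interaction. The SE of a log2 fold change is its absolute value over the square root of F. The biological coefficient of variation was 6.2%, with 4 residual degrees of freedom and a median prior of 8.7. The labels do not say whether replicates were separate cultures, so each p measures the spread between these samples. That spread was estimated per gene over all 4 groups together, so a p also draws on groups that are not compared. Between replicates, chi-square per degree of freedom was 2.54 in wild type at 30 °C, 1.86 in wild type at 37 °C, 4.03 in the knockout at 30 °C and 8.73 in the knockout at 37 °C, where counting error alone gives 1. Floors for genes at 0 were set at 3 counts over the group and cover counting error alone.

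Gene lists, 38 in number, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 35 lists with at least 4 tested members, and with an estimated correlation and fry as alternatives. The genes of each of 16 chromosomes were tested as sets in the same way. These tests, the lists, the comparisons and the rule for naming genes were fixed before the data were examined. The rule names RAD27 with 2 neighbours on each side and 7 genes of replication and the damage response. It adds the 5 largest rises and falls among genes past the threshold with a mean of at least 10 CPM over the 8 libraries and no overlap between the libraries of the 2 groups, and up to 3 members of each list described with the largest changes past the threshold. For the interaction no overlap was required. Which lists are described was chosen after their results were seen. Near-identical copies were found with blastn 2.17.0 (at least 95% identity over 50% of the length).

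Alternatives were median-of-ratios factors, library size alone, TMM without ribosomal protein genes, no filter or at least 5 CPM in 2 libraries, the older form of the quasi-likelihood test, a block on replicate number over all groups or within genotype, a test against a 1.5-fold change, the 4 libraries of a comparison alone, each library left out in turn, limma-voom and DESeq2 1.42.0. In a group left with 1 library, that library is assumed to vary like those of the other groups. Correlations of fold changes across genes are given without a p. The tests were checked on simulated data with 100 genes changed 1.5-fold and 100 changed 2-fold. They recovered from 54 of 100 (interaction) to 88 of 100 (knockout at 30 °C) at 1.5-fold and from 84 to 96 of 100 at 2-fold, and called 6 to 15 unchanged genes per comparison. A list raised in those data passed in all 5 comparisons, at both the preset and the estimated correlation, with 0 others called at the preset correlation. The simulated genes varied independently and with the same spread in all groups. The check therefore covers neither correlated genes nor groups of unequal spread. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.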

Results

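Polyadenylated RNA was sequenced from budding yeast, Saccharomyces cerevisiae, of 2 genotypes, a wild type and a strain with RAD27 knocked out, each grown at 30 or 37 °C. RAD27 encodes the flap endonuclease that trims the 5′ flaps of Okazaki fragments, the short pieces of the lagging strand, before they are ligated. The 8 libraries fell into 4 groups of 2, wild type at 30 °C, wild type at 37 °C, knockout at 30 °C and knockout at 37 °C. The series asked which changes in gene expression accompany faulty maturation of Okazaki fragments. Total counts ran from 4734266 to 5588983 per library, and 5667 genes had enough counts to be tested. Means ± SD over the 2 libraries of a group are in CPM, counts scaled to library size, and log2 fold changes are given ± SE. Principal component 1, with 61.6% of the variance, placed the knockout libraries at 37 °C at 33.8 and 43.6 and the other libraries between -22.5 and -6.6.

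RAD27 (YKL113C, chromosome XI, 224727 to 225875, minus strand, R64 assembly) had 0 counts in each of the 4 knockout libraries. In wild type its level was 114.2 ± 6.57 CPM at 30 °C and 93.6 ± 4.56 CPM at 37 °C. In wild type RAD27 itself was slightly lower at 37 than at 30 °C (-0.29 ± 0.09, adjusted p = 0.0313), a call lost in 6 of 15 other settings besides the test against a 1.5-fold change, among them leaving out any of the 4 wild type libraries. Against a floor of 3 counts over the group, RAD27 was at least 395-fold lower in the knockout at 30 °C and at least 355-fold lower at 37 °C. APN1, the neighbouring gene for an endonuclease of base excision repair (chromosome XI, 223352 to 224455), fell in the knockout from 96.1 ± 3.52 to 42.1 ± 5.18 CPM at 30 °C (log2 fold change -1.19 ± 0.11, adjusted p = 7.45e-06). At 37 °C APN1 fell from 92.3 ± 4.55 to 47.9 ± 4.31 CPM (-0.94 ± 0.10, adjusted p = 6.1e-06). On the other side, ABF1, which encodes a general regulatory factor, was lower by a smaller amount (-0.40 ± 0.09, adjusted p = 0.007 at 30 °C and -0.44 ± 0.10, adjusted p = 0.0019 at 37 °C). The call of ABF1 at 30 °C was lost without wild type replicate 2 at 30 °C or knockout replicate 2 at 30 °C. The next genes out, PRR1 and KTI12, did not pass at either temperature, with log2 fold changes of 0.08 and 0.02 at 30 °C and 0.07 and -0.14 at 37 °C. One further gene with at least 10 CPM in 1 genotype had 0 counts throughout the other, YCL021W-A, an open reading frame on chromosome III (83620 to 83997). YCL021W-A stood at 21.1 ± 5.55 and 23.0 ± 1.81 CPM in wild type at 30 and 37 °C and was at least 72-fold and 87-fold lower in the knockout. The labels do not say whether its locus is intact in the knockout strain.

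**Figure D1:**
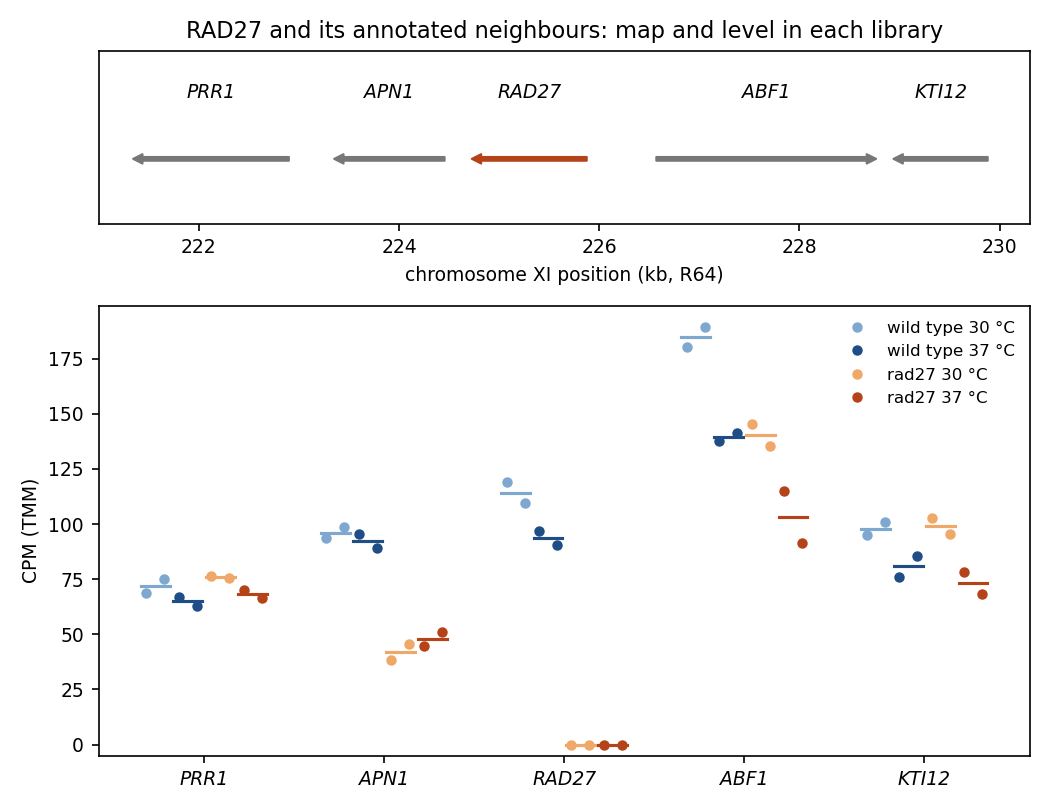
Map of RAD27 and the 2 annotated genes on each side on chromosome XI (kb, R64), with arrows in the direction of transcription, above their CPM in each library (points) and the group mean (lines). RAD27 was 0 in the 4 knockout libraries, and APN1 stood at 42.1 and 47.9 CPM in the knockout groups against 96.1 and 92.3 CPM in wild type.

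The first comparison asked how wild type cells responded to 4 hours at 37 °C. HSP82, for the inducible Hsp90, rose (log2 fold change 2.31 ± 0.14, adjusted p = 2.84e-07, from 274.3 ± 29.0 to 1358.9 ± 71.1 CPM). So did HSP26, a small heat shock protein (2.26 ± 0.13, adjusted p = 2e-07), and SSA1, a cytosolic Hsp70 whose reads can be shared with its near-identical copy SSA2 (2.08 ± 0.09, adjusted p = 1.36e-08). The stress protein gene HSP12 rose by 2.52 ± 0.17 (adjusted p = 7.3e-07). The phosphate transporter gene PHO89 showed the largest rise among genes with a mean of at least 10 CPM over the 8 libraries, 3.44 ± 0.56 (adjusted p = 0.000505, from 2.04 ± 0.04 to 22.3 ± 4.88 CPM). ARG1, for argininosuccinate synthase (-2.23 ± 0.21, adjusted p = 8.85e-06), and LEU1, for an enzyme of leucine synthesis (-1.82 ± 0.11, adjusted p = 2.34e-07), fell. IMD2, for the rate-limiting step of guanine nucleotide synthesis, fell by 1.85 on the log2 scale (SE 0.11, adjusted p = 2.34e-07). Across all genes, 891 were higher and 967 lower, 32.8% of those tested, and 110 and 63 of them changed at least 2-fold.

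Of 29 heat shock chaperone genes in wild type, 16 rose and 6 fell at 37 °C (17 and 6 adjusted over the list alone, camera adjusted p = 2.15e-10). Of 38 general stress genes, targets of Msn2 and Msn4, 20 rose and 0 fell (21 and 0 adjusted over the list alone, adjusted p = 6.45e-13). With an estimated correlation between genes the adjusted p of those lists was 0.416 and 0.451, and neither passed. Ribosomal protein genes fell together, 127 of 137 with 4 higher (129 and 4 adjusted over the list alone, adjusted p = 2.08e-51, and adjusted p = 0.451 with an estimated correlation). RPS31 and RPS21A stood at -0.93 ± 0.08 and -0.91 ± 0.10. Genes of the TCA cycle and respiratory chain fell in 37 of 42 cases with 1 higher (38 and 1 adjusted over the list alone, adjusted p = 1.32e-21, and adjusted p = 0.416 with an estimated correlation). Examples were ACO1, for aconitase (-1.15 ± 0.07), CYT1, for cytochrome c1 (-1.11 ± 0.14), and COX4, for a subunit of cytochrome c oxidase (-1.11 ± 0.11). Cell wall integrity genes rose in 12 of 16 cases with 1 lower (12 and 1 adjusted over the list alone, adjusted p = 4.8e-11, and adjusted p = 0.416 with an estimated correlation). The largest rises were those of GSC2, a glucan synthase gene (1.64 ± 0.08), the wall mannoprotein gene CWP1 (1.34 ± 0.11) and RLM1, a transcription factor of that pathway (1.01 ± 0.08). In the phosphate regulon 13 of 16 rose and 0 fell (14 and 0 adjusted over the list alone, adjusted p = 2.32e-08, and adjusted p = 0.451 with an estimated correlation). SPL2 was among them (2.02 ± 0.26). PHO84, the main high-affinity phosphate transporter gene, rose by 1.53 ± 0.23, although an antisense non-coding gene overlaps it and strand use in the counting is not given.

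Amino acid biosynthesis genes under Gcn4 fell in 24 of 40 cases with 2 higher in wild type at 37 °C (26 and 2 adjusted over the list alone, adjusted p = 9.49e-10, and adjusted p = 0.451 with an estimated correlation). HIS4 was among them (-1.29 ± 0.16). Genes of the M/G1 transition in daughter cells, which act in cell separation, rose in 8 of 13 cases with 0 lower (9 and 1 adjusted over the list alone, adjusted p = 2.14e-05, and adjusted p = 0.416 with an estimated correlation). The largest rises were those of SCW11 (1.06 ± 0.08), DSE4 (0.70 ± 0.11) and DSE1 (0.68 ± 0.06). Histone genes fell in 7 of 9 cases (7 adjusted over the list alone, adjusted p = 0.0036, and adjusted p = 0.456 with an estimated correlation). HHT1, for histone H3, was among them (-0.70 ± 0.08). The DNA damage-induced list did not pass (adjusted p = 0.0843, 6 of 18 higher and 2 lower, 7 and 2 adjusted over the list alone). Within it the repair genes MAG1, RAD16 and RAD2 rose by 0.94 ± 0.15, 0.91 ± 0.09 and 0.78 ± 0.07, whereas RNR3 (0.49 ± 0.25, adjusted p = 0.146) and HUG1 (0.68 ± 0.30, adjusted p = 0.106) did not pass. DUN1, the kinase that acts on ribonucleotide reductase in the damage checkpoint, fell by 0.65 on the log2 scale (SE 0.12, adjusted p = 0.0014), and POL30, for the sliding clamp PCNA, by 0.59 (SE 0.09, adjusted p = 0.000311). Scaling by library size alone moved the median of all genes by 0.13 on the log2 scale and gave 1497 higher and 596 lower. The total fell from 1858 to 1121 genes without wild type replicate 2 at 30 °C and to 1044 without wild type replicate 1 at 37 °C.

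The second comparison put the same temperature step in the knockout. HSP26 rose by 6.28 ± 0.11 on the log2 scale (adjusted p = 7.77e-13), HSP12 by 5.17 ± 0.17 (adjusted p = 3.28e-10, from 22.7 ± 7.32 to 818.6 ± 139.9 CPM) and TDH1, for an isozyme of glyceraldehyde-3-phosphate dehydrogenase, by 4.65 ± 0.11 (adjusted p = 1.21e-11, from 56.5 ± 9.91 to 1419.5 ± 33.8 CPM). GAC1, for a regulatory subunit of the phosphatase that acts on glycogen synthase, rose by 4.74 ± 0.32 (adjusted p = 1.44e-07). The DNA damage genes RNR3, a ribonucleotide reductase subunit, and HUG1, a small inhibitor of that enzyme, rose by 2.23 ± 0.13 (adjusted p = 3.08e-08) and 2.00 ± 0.12 (adjusted p = 4.23e-08). Among the falls, the log2 fold change was -2.95 for LEU1, -2.29 for LEU2, -2.19 for GDH1, a glutamate dehydrogenase gene, and -2.17 for BAT1, a branched-chain aminotransferase gene. The count was 1751 higher and 1596 lower, 59.1% of the genes tested, with 519 and 119 changed at least 2-fold.

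General stress genes rose in 37 of 38 cases in the knockout at 37 °C against 30 °C (37 adjusted over the list alone, adjusted p = 2.52e-39, and adjusted p = 0.22 with an estimated correlation). Their median log2 fold change was 1.95. DDR2, a stress gene, rose by 3.69 ± 0.26 (4.54 without knockout replicate 2 at 30 °C). Ribosomal protein genes fell in 132 of 137 cases with 0 higher (133 adjusted over the list alone, adjusted p = 1.06e-56, and adjusted p = 0.257 with an estimated correlation). Ribosome biogenesis genes fell in 70 of 81 with 0 higher (72 adjusted over the list alone, adjusted p = 2.97e-13, and adjusted p = 0.327 with an estimated correlation). Examples were BFR2 (-1.08 ± 0.11) and UTP18 (-0.92 ± 0.11). The DNA damage-induced list rose in 16 of 18 cases with 1 lower (16 and 1 adjusted over the list alone, adjusted p = 1.65e-06, and adjusted p = 0.22 with an estimated correlation). PHR1, for photolyase, was among them (1.39 ± 0.17). M/G1 daughter cell genes fell in 11 of 13 cases with 0 higher (11 adjusted over the list alone, adjusted p = 3.28e-06, and adjusted p = 0.22 with an estimated correlation). DSE4 stood at -1.49 and EGT2 at -1.28 on the log2 scale. All 9 histone genes fell (9 adjusted over the list alone, adjusted p = 2.04e-05, and adjusted p = 0.395 with an estimated correlation). HTA2 stood at -1.16 and HTB2 at -1.13.

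Cell wall integrity genes rose in 13 of 16 cases with 1 lower in the knockout (13 and 1 adjusted over the list alone, adjusted p = 3.56e-10, and adjusted p = 0.257 with an estimated correlation). PIR3, a wall glycoprotein gene, rose by 4.60 ± 0.28. Methionine and sulfur genes fell in 13 of 19 cases with 0 higher (14 adjusted over the list alone, adjusted p = 1.4e-08, and adjusted p = 0.22 with an estimated correlation). Examples were MET6, for methionine synthase (-1.99 ± 0.10), and MET14, for an enzyme of sulfate assimilation (-1.65 ± 0.11). Of 14 genes for gluconeogenesis and fatty acid use, 11 rose and 0 fell (12 and 0 adjusted over the list alone, adjusted p = 0.0178, and adjusted p = 0.683 with an estimated correlation). That list did not pass without knockout replicate 1 at 30 °C (adjusted p = 0.0525). Levels differed widely between the knockout libraries at 37 °C, with PCK1, for the first step of gluconeogenesis, at 114.6 ± 94.3 CPM and JEN1, a lactate transporter gene, at 55.9 ± 38.7 CPM. The heat shock chaperone list did not pass (adjusted p = 0.176, 13 of 29 higher and 11 lower, the same counts adjusted over the list alone), though it did without knockout replicate 2 at 37 °C (adjusted p = 0.0273). SSA4 and SSE2, for Hsp70 family chaperones, rose by 1.57 ± 0.08 and 1.55 ± 0.10. MATa-specific genes fell in 6 of 7 cases with 1 higher (6 and 1 adjusted over the list alone, adjusted p = 5.24e-05, and adjusted p = 0.333 with an estimated correlation). The same list also fell with temperature in wild type, 4 of 7 with 0 higher (camera adjusted p = 0.000793, and adjusted p = 0.451 with an estimated correlation). In the knockout STE3 and SAG1, markers of the other mating type, rose by 1.31 ± 0.31 (1.95 without knockout replicate 1 at 30 °C) and 0.69 ± 0.12. STE3 stayed low, going from 3.57 to 8.84 CPM. Scaling by library size alone shifted the median of all genes by 0.24 and gave 2803 higher and 842 lower.

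**Figure D2:**
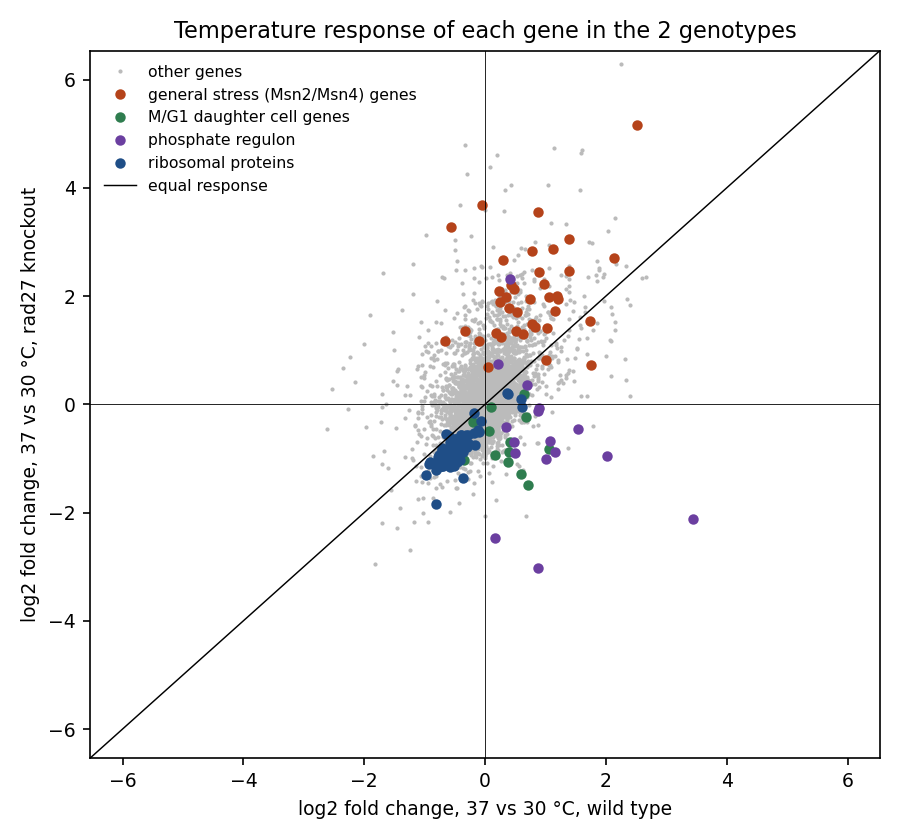
Log2 fold change of each gene from 30 to 37 °C in wild type (horizontal axis) and in the knockout (vertical axis), with 4 gene lists coloured and a line of equal response, leaving out RAD27 and YCL021W-A, which had 0 counts in the knockout. The general stress genes had a median of 0.76 in wild type and 1.95 in the knockout, and the M/G1 daughter cell genes a median of 0.40 and -0.83.

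The third comparison, knockout against wild type at 30 °C, asked what loss of RAD27 changed without heat. HUG1 rose from 4.59 ± 0.506 to 38.9 ± 4.82 CPM (log2 fold change 3.07 ± 0.22, adjusted p = 1.28e-06) and RNR3 from 11.5 ± 1.69 to 62.3 ± 15.6 CPM (2.44 ± 0.20, adjusted p = 3.66e-06). The kinase gene DUN1 rose by 0.60 ± 0.11 (adjusted p = 0.0013). Among genes with a mean of at least 10 CPM over the 8 libraries, PHO89 showed the largest rise (4.81 ± 0.47, adjusted p = 1.62e-05, 57.9 ± 25 CPM in the knockout). After RAD27 and YCL021W-A, the largest fall among them was that of URA1, for dihydroorotate dehydrogenase of pyrimidine synthesis (-3.08 ± 0.07, adjusted p = 1.1e-11, from 1250.3 ± 36.9 to 148.3 ± 0.784 CPM). Next came MDH2, for cytosolic malate dehydrogenase (-2.82 ± 0.19, adjusted p = 7.71e-07), and RIB4, of riboflavin synthesis (-1.89 ± 0.07, adjusted p = 5.36e-09). The count was 829 higher and 851 lower, 29.6% of the genes tested, with 90 and 71 changed at least 2-fold.

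DNA damage-induced genes were higher in 13 of 18 cases and lower in 2 at 30 °C (13 and 3 adjusted over the list alone, adjusted p = 2.39e-12, and adjusted p = 0.0993 with an estimated correlation). PLM2, a transcription factor gene, rose by 1.65 ± 0.17. Homologous recombination genes were higher in 6 of 20 cases and lower in 0 (6 and 0 adjusted over the list alone, adjusted p = 0.0016, and adjusted p = 0.377 with an estimated correlation). TOP3 was among them (0.83 ± 0.16). The Okazaki fragment maturation list did not pass (adjusted p = 0.609, 3 of 18 higher and 1 lower, the same counts adjusted over the list alone). In it CDC9, for DNA ligase I, and RFC3, for a subunit of the clamp loader, rose by 0.44 ± 0.07 and 0.42 ± 0.08, and RNH1, for ribonuclease H1, fell by 0.58 on the log2 scale. POL3 (0.04 ± 0.08), POL30 (-0.08 ± 0.09), DNA2 (0.03 ± 0.08) and EXO1 (0.11 ± 0.09), for the lagging strand polymerase, its clamp and the nucleases that can also act on flaps, did not pass.

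Methionine and sulfur genes were higher in 16 of 19 cases and lower in 0 in the knockout at 30 °C (17 and 0 adjusted over the list alone, adjusted p = 1.44e-14, and adjusted p = 0.0993 with an estimated correlation). The largest rises were those of the sulfate permease genes SUL1 (2.43 ± 0.40) and SUL2 (1.72 ± 0.15) and MET2 (2.33 ± 0.15). Proteasome genes rose in 26 of 34 cases with 0 lower (29 and 0 adjusted over the list alone, adjusted p = 5.01e-11, and adjusted p = 0.0556 with an estimated correlation). PUP3 and PRE6, both for core subunits, rose by 0.59 ± 0.06 and 0.55 ± 0.07. The phosphate regulon was higher in 9 of 16 cases and lower in 1 (11 and 1 adjusted over the list alone, adjusted p = 1.25e-07, and adjusted p = 0.489 with an estimated correlation). The acid phosphatase genes PHO12 and PHO11, near-identical copies that can share reads, rose by 2.67 ± 0.29 and 2.26 ± 0.33. Iron regulon genes were higher in 8 of 16 and lower in 2 (8 and 2 adjusted over the list alone, adjusted p = 0.0032, and adjusted p = 0.489 with an estimated correlation). The largest rises were those of the wall mannoprotein genes FIT2 (2.45 ± 0.27) and FIT3 (1.97 ± 0.15). M/G1 daughter cell genes fell in 8 of 13 cases with 1 higher (8 and 2 adjusted over the list alone, adjusted p = 6.05e-11, and adjusted p = 0.0993 with an estimated correlation). Examples were DSE1 (-1.42 ± 0.07), the chitinase gene CTS1 (-1.24 ± 0.07) and DSE2 (-1.21 ± 0.07).

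Histone genes fell in 7 of 9 cases in the knockout at 30 °C with 0 higher (8 and 0 adjusted over the list alone, adjusted p = 0.000359, and adjusted p = 0.489 with an estimated correlation). Ribosome biogenesis genes fell in 37 of 81 with 0 higher (41 and 0 adjusted over the list alone, adjusted p = 7.54e-11, and adjusted p = 0.489 with an estimated correlation). CIC1 stood at -0.86 and BRX1 at -0.76 on the log2 scale. General stress genes were already higher without heat in 18 of 38 cases (0 lower, camera adjusted p = 1.94e-07). So were 15 of 29 heat shock chaperone genes (1 lower, adjusted p = 3.78e-06). Cell wall integrity genes were higher in 9 of 16 (1 lower, adjusted p = 0.000275). For amino acid biosynthesis it was 18 of 40 (1 lower, adjusted p = 4.61e-08). With an estimated correlation the adjusted p was 0.42 for the chaperones and 0.489 for the others. Auxotrophic marker genes, which differ between laboratory strains, were higher in 3 of 6 cases and lower in 0 (3 and 0 adjusted over the list alone, adjusted p = 7.78e-07, and adjusted p = 0.175 with an estimated correlation). MET17 rose by 1.70 ± 0.08, LEU2 by 1.44 ± 0.11 and URA3 by 1.10 ± 0.09. HIS3 had 0 counts in all 8 libraries and ADE2 at most 3 per library, so neither was tested. TRP1 stayed low in both genotypes, with group means of 0.956 to 2.36 CPM. Whether the higher MET17, LEU2 and URA3 mark a strain difference or regulation of those genes was not tested. In the knockout against wild type at 37 °C the values were 0.61 ± 0.13 for LEU2, 1.70 ± 0.09 for URA3 and -0.24 ± 0.08 for MET17. The difference in MET17 thus changed direction with temperature. MATa-specific genes did not pass as a list (adjusted p = 0.357, 0 of 7 higher and 2 lower, the same counts adjusted over the list alone). The other mating type was marked by MF(ALPHA)1 and STE3, which stood at 0.864 and 3.57 CPM in the knockout at 30 °C and at 0.532 and 2.38 CPM in wild type at 30 °C. The total fell from 1680 genes to 972 and 1005 when wild type replicate 1 or 2 at 30 °C was left out and to 1087 without knockout replicate 2 at 30 °C, and DESeq2 called 1075.

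**Figure D3:**
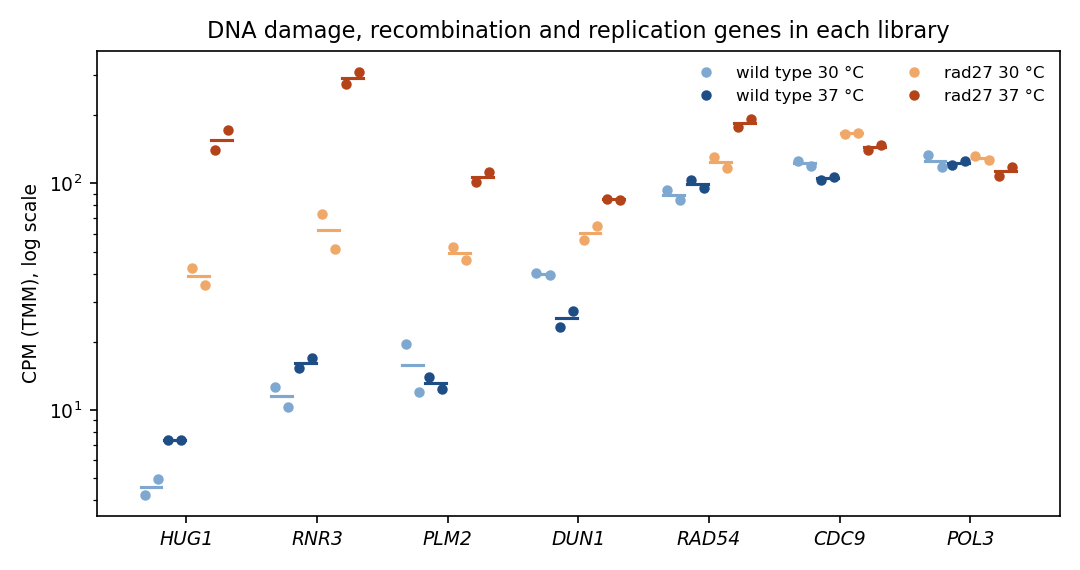
CPM (log axis) of genes of the DNA damage response, recombination and replication in each of the 8 libraries (points) with the group mean (lines). HUG1 rose from 4.59 CPM in wild type at 30 °C to 155.6 CPM in the knockout at 37 °C, and POL3 stayed between 113.3 and 129.1 CPM in the 4 groups.

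The fourth comparison was knockout against wild type at 37 °C. HUG1 stood at 155.6 ± 22.7 CPM against 7.37 ± 0.0219 (log2 fold change 4.40 ± 0.16, adjusted p = 5.19e-10) and RNR3 at 291.8 ± 26.0 against 16.2 ± 1.15 (4.17 ± 0.15, adjusted p = 6.99e-10). PLM2 rose by 3.02 ± 0.16 (adjusted p = 1.37e-08) and DUN1 by 1.74 ± 0.11 (adjusted p = 7.63e-08). PIR3 (4.88 ± 0.29, adjusted p = 5.06e-08), GLC3, for the glycogen branching enzyme (4.50 ± 0.38, adjusted p = 9.36e-07, and 361.9 ± 217.3 CPM in the knockout), EGO4 (4.49 ± 0.28, adjusted p = 8.75e-08) and RGI1 (4.31 ± 0.36, adjusted p = 9.36e-07) were the other genes with the largest rises among those with a mean of at least 10 CPM over the 8 libraries. Without knockout replicate 2 at 37 °C, GLC3 stood at 3.69 and RGI1 at 3.59. ARG1 and ARG3, of arginine synthesis, rose, ARG1 from 34.2 ± 1.17 to 642.9 ± 99.2 CPM (4.23 ± 0.20, adjusted p = 5.13e-09) and ARG3 by 3.64 ± 0.17 (adjusted p = 6.54e-09). EGT2 and SCW11, of cell separation, fell, with log2 fold changes of -2.46 for EGT2 and -2.42 for SCW11 (adjusted p = 9.76e-10 and adjusted p = 6.68e-10). PRY3, for a wall-associated protein, fell by 2.52 on the log2 scale (adjusted p = 3.07e-10). The count was 1731 higher and 1656 lower, 59.8% of the genes tested, with 494 and 81 changed at least 2-fold.

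DNA damage-induced genes were higher in 13 of 18 cases and lower in 2 at 37 °C (13 and 2 adjusted over the list alone, adjusted p = 1.08e-14, and adjusted p = 0.0933 with an estimated correlation). Homologous recombination genes were higher in 12 of 20 and lower in 0 (12 and 0 adjusted over the list alone, adjusted p = 0.0248, and adjusted p = 0.455 with an estimated correlation). RAD54, for a DNA translocase, rose by 0.89 ± 0.09 and TOP3, for a topoisomerase, by 0.68 ± 0.14. That list did not pass without wild type replicate 2 (adjusted p = 0.0523) or knockout replicate 1 at 37 °C (adjusted p = 0.0855). The Okazaki fragment maturation list did not pass (adjusted p = 0.848, 4 of 18 higher and 4 lower, 4 and 3 adjusted over the list alone). CDC9 and EXO1 rose in it by 0.45 ± 0.07 and 0.41 ± 0.09, whereas POL3 (-0.12 ± 0.08, adjusted p = 0.24) and POL30 (0.22 ± 0.09, adjusted p = 0.0503) did not pass. DNA2 was lower by a small amount (-0.22 ± 0.08, adjusted p = 0.0272), a call lost in 6 of 14 other settings besides the test against a 1.5-fold change, among them leaving out either wild type library or knockout replicate 2 at 37 °C.

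All 38 general stress genes rose in the knockout at 37 °C (38 adjusted over the list alone, adjusted p = 3.6e-33, and adjusted p = 0.269 with an estimated correlation). DDR2 rose by 3.39 ± 0.25 and the transcription factor gene USV1 by 3.20 ± 0.34 (2.47 without knockout replicate 2 at 37 °C). Of 14 genes for gluconeogenesis and fatty acid use, 12 rose and 1 fell (12 and 1 adjusted over the list alone, adjusted p = 0.0137, and adjusted p = 0.759 with an estimated correlation). Genes of the TCA cycle and respiratory chain were higher than in wild type in 38 of 42 cases with 0 lower (38 and 0 adjusted over the list alone, adjusted p = 5.33e-11, and adjusted p = 0.455 with an estimated correlation). With temperature that list fell in wild type (37 of 42 lower). In the knockout it did not pass with temperature (13 higher and 3 lower, camera adjusted p = 0.386). The largest differences from wild type were those of the succinate dehydrogenase genes SDH1 (1.72 ± 0.12) and SDH2 (1.63 ± 0.11). Cell wall integrity genes rose in 13 of 16 with 1 lower (13 and 1 adjusted over the list alone, adjusted p = 8.35e-06, and adjusted p = 0.455 with an estimated correlation). The yapsin protease gene YPS3 rose by 2.27 ± 0.11. Amino acid biosynthesis genes were higher than in wild type in 24 of 40 with 1 lower (26 and 1 adjusted over the list alone, adjusted p = 7.1e-08, and adjusted p = 0.469 with an estimated correlation). They too fell with temperature in wild type (24 of 40 lower). As a list they did not pass with temperature in the knockout (13 higher and 15 lower, camera adjusted p = 0.176). ARG56, which encodes further enzymes of arginine synthesis, rose by 2.04 ± 0.11.

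M/G1 daughter cell genes fell in 11 of 13 cases with 0 higher in the knockout at 37 °C, with a median of -2.16 (11 adjusted over the list alone, adjusted p = 1.08e-29, and adjusted p = 0.0554 with an estimated correlation). Histone genes fell in 8 of 9 with 1 higher (8 and 1 adjusted over the list alone, adjusted p = 5.37e-06, and adjusted p = 0.455 with an estimated correlation). HTB2 stood at -1.79 and HTA2 at -1.39 on the log2 scale. All 81 ribosome biogenesis genes fell (81 adjusted over the list alone, adjusted p = 3e-27, and adjusted p = 0.269 with an estimated correlation). UTP18 was among them (-1.09 ± 0.11). Genes of the CLB2 cluster of G2/M went both ways and the list did not pass (adjusted p = 0.944, 6 of 18 higher and 7 lower, the same counts adjusted over the list alone), with a median of -0.09 that turned to 0.04 under library size alone and a mean of 0.07. In that cluster SPO12, of mitotic exit, rose by 1.05 ± 0.09 and the cyclin gene CLB1 by 0.80 ± 0.08. Scaling by library size alone shifted the median of all genes by 0.13 and gave 2182 higher and 1123 lower.

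**Figure D4:**
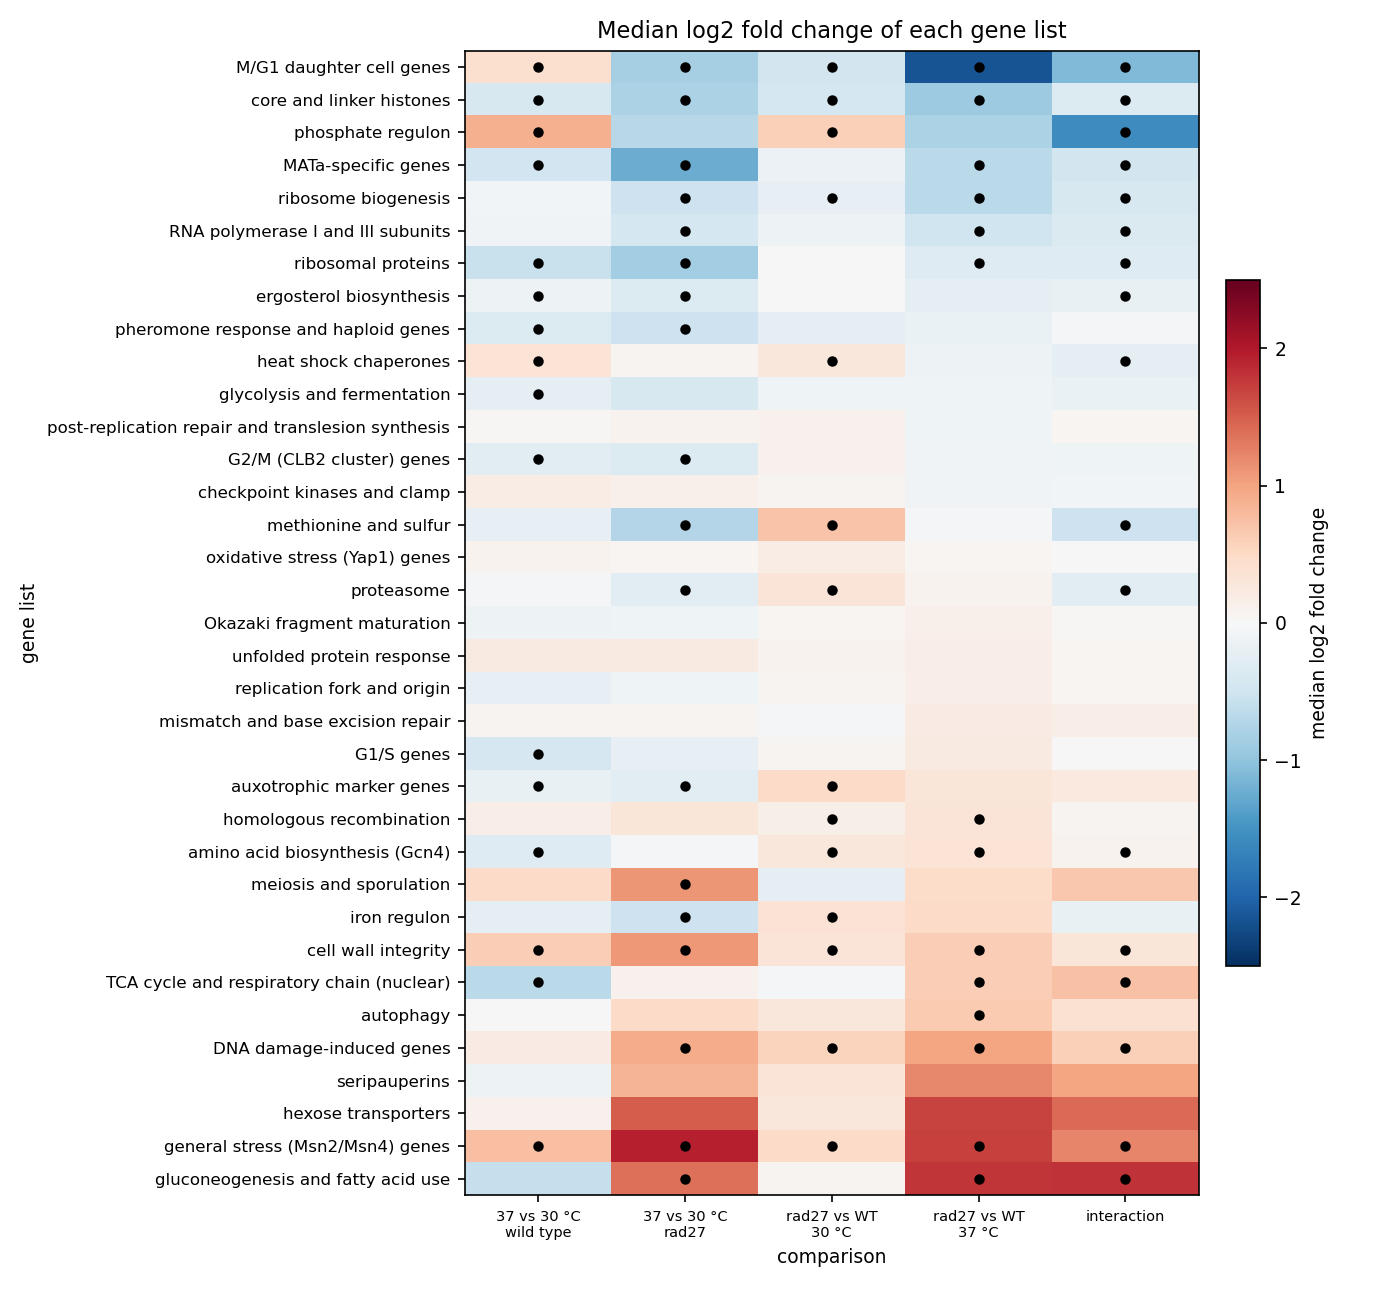
Median log2 fold change (colour scale) of the 35 gene lists with at least 4 tested members in each of the 5 comparisons, with a dot where camera passed at its preset correlation, none of which passed with an estimated correlation. Lists are sorted by their median in the knockout against wild type at 37 °C, from -2.16 for the M/G1 daughter cell genes to 1.79 for gluconeogenesis and fatty acid use.

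The fifth comparison tested whether the temperature response differed between genotypes. HSP26 rose by 4.03 ± 0.20 more on the log2 scale in the knockout than in wild type (adjusted p = 1.19e-07). The interaction was 4.40 ± 0.65 for PIR3 (adjusted p = 0.000374), 4.55 ± 0.65 for EGO4 (adjusted p = 0.00029) and 4.11 ± 0.39 for HSP30, for a plasma membrane stress protein (adjusted p = 1.56e-05). HSP30 went from 27.7 ± 7.58 to 14.1 ± 1.96 CPM with temperature in wild type and from 12.1 ± 1.40 to 106.6 ± 34.8 CPM in the knockout. The interaction was also positive for RNR3 (1.74 ± 0.29, adjusted p = 0.000781) and for DUN1 (1.14 ± 0.16, adjusted p = 0.000214), which fell in wild type and rose in the knockout (0.49 ± 0.10). For HUG1 the difference was 1.33 ± 0.34 (adjusted p = 0.0104), a call lost without wild type replicate 2 at 30 °C. A negative interaction was found for PHO89 (-5.55 ± 0.62, adjusted p = 5.12e-05), SPL2 (-2.98 ± 0.34, adjusted p = 5.88e-05) and CAR2, of arginine breakdown (-2.19 ± 0.13, adjusted p = 3.37e-07). The interaction was positive in 930 genes and negative in 972, 33.6% of those tested, with 340 and 66 of at least 2-fold.

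General stress genes had a positive interaction in 32 of 38 cases and a negative one in 0 (34 and 0 adjusted over the list alone, adjusted p = 1.75e-19, and adjusted p = 0.361 with an estimated correlation). Examples were GLC3 (3.84 ± 0.64, and 3.03 without knockout replicate 2 at 37 °C) and DDR2 (3.73 ± 0.53, and 4.59 without knockout replicate 2 at 30 °C). TCA cycle and respiratory chain genes, which fell in wild type, had a positive interaction in 38 of 42 cases and a negative one in 1 (38 and 1 adjusted over the list alone, adjusted p = 9.17e-18, and adjusted p = 0.358 with an estimated correlation). The interaction was 1.64 ± 0.17 for SDH1 and 1.59 ± 0.16 for SDH2. DNA damage-induced genes were positive in 11 of 18 and negative in 2 (11 and 2 adjusted over the list alone, adjusted p = 0.000311, and adjusted p = 0.358 with an estimated correlation). For the M/G1 daughter cell genes the interaction was negative in 11 of 13 and positive in 0 (11 adjusted over the list alone, adjusted p = 1.75e-19, and adjusted p = 0.127 with an estimated correlation). For DSE4 it was -2.20 ± 0.17. The phosphate regulon was negative in 13 of 16 and positive in 1 (13 and 1 adjusted over the list alone, adjusted p = 1.63e-09, and adjusted p = 0.417 with an estimated correlation).

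Methionine and sulfur genes had a negative interaction in 10 of 19 cases and a positive one in 0 (11 and 1 adjusted over the list alone, adjusted p = 4.22e-07, and adjusted p = 0.358 with an estimated correlation). For MET2 it was -1.85 ± 0.22. Proteasome genes were negative in 16 of 34 and positive in 1 (17 and 1 adjusted over the list alone, adjusted p = 0.000311, and adjusted p = 0.238 with an estimated correlation). The positive one was RPN4, the transcription factor of proteasome genes (0.79 ± 0.21). Heat shock chaperone genes split, 8 of 29 positive and 14 negative (8 and 16 adjusted over the list alone, adjusted p = 0.001, and adjusted p = 0.488 with an estimated correlation). HSP26 was positive and the near-identical pair SSA1 and SSA2 was negative, at -1.56 ± 0.12 and -1.64 ± 0.16. At 30 °C SSA1 already stood at 961.5 CPM in the knockout against 452.3 CPM in wild type, and SSA2 at 2962.7 against 2429.1 CPM. With library size alone the median of all genes shifted by 0.11 and the split was 1197 positive and 604 negative, and DESeq2 called 559 positive and 800 negative.

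Across genes, the log2 temperature responses of the genotypes correlated with Pearson's r 0.457 and Spearman's rho 0.46, and the knockout effects at 30 and 37 °C with r 0.5 and rho 0.444. The knockout effects include RAD27 (-12.22 and -11.93) and YCL021W-A (-9.77 and -9.91). Their large falls at both temperatures follow from 0 counts in every knockout library and can raise r, which was not computed without them. Genes are not independent replicates, so no p is given, and neither pair of comparisons shared a library. Without a filter on low counts r was 0.26 and 0.306. With temperature, 527 genes rose in both genotypes and 625 fell in both, the latter against 272 for independent lists, and 164 went in opposite directions, against 550. For the knockout effect 499 genes were higher at both temperatures against 253, 537 lower at both against 249, and 150 opposite against 502.

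Because strains without RAD27 are known for genome instability, the genes of each of the 16 nuclear chromosomes were tested as a set. With camera on the edgeR fit, 0 chromosomes passed in any of the 5 comparisons, and the count at an unadjusted p under 0.05 was 1 in wild type with temperature, 1 in the knockout at 30 °C and 0 in the other comparisons. With an estimated correlation 0 passed too, and the counts at an unadjusted p under 0.05 were the same. The smallest adjusted p, 0.189, was that of chromosome I in the knockout at 30 °C. Chromosome medians of the log2 fold changes lay between -0.054 and 0.167, the highest for chromosome I in the knockout at 37 °C. In single libraries, chromosome medians against the other replicate stayed between -0.034 and 0.034, a contrast in which a change shared by both replicates would not show. Against the other libraries they ran from -0.106 in wild type replicate 1 at 30 °C to 0.147 in knockout replicate 2 at 37 °C, both for chromosome I.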

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

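The tests of scaling, of hexose transporter genes, of the pyrimidine pathway and of early G1 genes below took their final form after their results were seen, and the 3 patterns were chosen after the comparisons were seen. The genes named beyond the rule (the hexose transporters, URA2 to URA10 other than URA3, URA1, URA3, MET17 and LEU2 in the knockout against wild type at 37 °C, SWI4, the MCM genes and the mating type markers STE3, SAG1 and MF(ALPHA)1) were also chosen after their values were seen. So were HIS3, ADE2 and TRP1. The second pattern below is a knockout effect seen at both temperatures. What singled out the other results here is a difference between the temperature responses of the genotypes, tested as an interaction. It passed for 1902 genes and for 17 gene lists at the preset correlation of camera, and for 0 lists with an estimated correlation, where 4 had an unadjusted p under 0.05 and fry called 13.

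The first pattern is that general stress genes rose more with temperature in the knockout. The choice among 4 scalings is argued against only in that the pattern held under each. The lowest median interaction of that list, not centred on all genes, was 1.20 under them. The scalings differed little, as library size alone moved the median of all genes by 0.11, so that test could hardly have failed. All are relative to the counts of a library, so a change in total RNA was not tested. A single divergent knockout library at 37 °C is argued against too, since 33 members were called without replicate 1 and 31 without replicate 2. Glucose exhaustion in the knockout culture at 37 °C may contribute and stays open. In its first form the test asked only whether HXT1 and HXT3 were lower in the knockout at 37 °C, and 2 of 2 were (-1.75 and -0.36). After that value was seen, a lower value in the interaction was also required, which only 1 of 2 met (HXT1 -1.56, HXT3 0.01). Outside that test, the interaction was positive for HXT4, HXT6 and HXT7 (2.15, 3.59 and 1.79), whereas HXT2 (-0.92) and HXT5 (1.41) did not pass. HXT6 and HXT7 are near-identical copies. Genes for gluconeogenesis and fatty acid use were also mostly higher in the knockout at 37 °C, as given above. Of these PCK1 (47.9 and 181.3 CPM), like HXT2 (572.7 and 1417.6 CPM), differed widely between the 2 knockout libraries at 37 °C. A direct effect of the knockout was not tested.

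The second pattern is that URA1 was lower in the knockout (-3.08 at 30 °C and -2.01 at 37 °C) while URA3 was higher (1.10 and 1.70). URA3 as a marker gene of the knockout strain could lower other targets of the regulator Ppr1, and of 4 tests of URA4 and URA10, 2 called them lower (URA4 at -1.41 and -0.94), whereas URA10 was higher at 37 °C (1.44). Lower expression of the whole pyrimidine pathway is argued against at 30 °C, where the highest of URA2, URA5, URA6 and URA7 was URA6 at 0.08 ± 0.08 and only URA2 was called lower (-0.69). At 37 °C it may apply, as 4 of 4 were called lower, by less than URA1, with URA6 highest at -0.27, between the bounds set. In its first form that test counted 5 of 8 over both temperatures, and the marker at both temperatures and the pathway at 37 °C cannot be told apart, since the labels give no marker and no other biological explanation was tested.

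The third pattern is the fall of M/G1 daughter cell genes in the knockout at 37 °C. The choice among 4 scalings is argued against only in that the pattern held under each. The highest median of that list, not centred on all genes, was -2.03 under them. The scalings differed little, as library size alone moved the median of all genes by 0.13, so that test could hardly have failed. All are relative to the counts of a library, so a change in total RNA was not tested. Fewer cells in M/G1 could contribute and stays open. The median of 8 early G1 genes was -0.10, above the bound of -0.25 written for the test, but the reading was changed to open after this value was seen because 2 were called lower (SWI4, MCM6) and 2 higher (MCM5, MCM7).

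Other genes whose responses differed are given as log2 interactions. In DNA damage genes these were 1.14 for DUN1, 1.74 for RNR3, 1.33 for HUG1, 1.69 for PHR1 and 1.37 for PLM2. The call of HUG1 was lost without wild type replicate 2 at 30 °C. Stress, wall and carbon genes stood at 4.55 for EGO4, 4.40 for PIR3, 4.11 for HSP30, 4.09 for RGI1, 4.03 for HSP26, 3.84 for GLC3, 3.73 for DDR2 and 2.68 for USV1, whose call was also lost without that library. Without knockout replicate 2 at 37 °C, RGI1 stood at 3.38, GLC3 at 3.03 and USV1 at 1.95, and without knockout replicate 2 at 30 °C DDR2 stood at 4.59. Respiratory genes stood at 1.64 for SDH1, 1.59 for SDH2 and 1.56 for ATP20. In the phosphate regulon PHO89 stood at -5.55, PHO12 at -3.91 and SPL2 at -2.98. Cell separation genes stood at -2.20 for DSE4, -1.89 for SCW11 and -1.87 for EGT2. Methionine genes stood at -2.07 for MMP1, -1.85 for MET2 and -1.46 for MET14, and CAR2 at -2.19. Proteasome genes stood at 0.79 for RPN4, -0.62 for RPT1 and -0.59 for PRE2, and the near-identical chaperone genes SSA2 and SSA1 at -1.64 and -1.56.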

How the results depend on the processing

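The alternatives below were planned before the data were examined, and none was added later. In 0 settings was a gene called in the direction opposite to its call in the edgeR fit, and 0 of the 232 named gene results reversed. Under limma-voom 232 of those 232 kept their direction and side of the threshold, under DESeq2 227, under library size alone 220 and against a 1.5-fold change 183.

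Tested against a 1.5-fold change, a stricter question, 129 genes passed with temperature in wild type (69 higher and 60 lower), 848 in the knockout (545 and 303), 88 for the knockout at 30 °C (54 and 34), 724 at 37 °C (549 and 175) and 285 in the interaction (212 and 73). Library size alone gave 1497 higher and 596 lower with temperature in wild type, 2803 and 842 in the knockout and 604 lower in the interaction, since it leaves out the shift that TMM removes. It put the level of RAD27 in wild type at 30 °C at 106.9 CPM. DESeq2 called 574 higher with temperature in wild type, 1075 in all and 520 lower for the knockout at 30 °C, and 559 higher in the interaction, and the cause was not tested. Without a filter on low counts the correlations were 0.26 for temperature and 0.306 for the knockout, on 6468 genes. With the 4 libraries of a comparison alone, totals rose from 1858 to 2402 for temperature in wild type and from 1680 to 2028 for the knockout at 30 °C. They fell from 3347 to 3000 for temperature in the knockout and from 3387 to 3146 for the knockout at 37 °C.

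With an estimated correlation camera called 0 lists with temperature in wild type, 0 in the knockout, 0 for the knockout at 30 °C, 0 at 37 °C and 0 in the interaction, with 4, 6, 5, 4 and 4 at an unadjusted p under 0.05. The smallest adjusted p there was 0.416, 0.22, 0.0556, 0.0554 and 0.127. Fry called 23, 29, 17, 22 and 13 lists.

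With each library left out in turn, totals ran from 1044 to 1263 for temperature in wild type, 2832 to 3402 in the knockout, 972 to 1157 for the knockout at 30 °C, 2740 to 3451 at 37 °C and 1339 to 2388 in the interaction. In wild type 479 to 605 were higher (566 without replicate 1 at 30 °C) and 553 to 697 lower, and for the knockout at 30 °C 482 to 577 and 487 to 580. Fewer libraries remain in those fits, and totals moved by over 1.5 times without wild type replicate 2 at 30 °C (1121) or replicate 1 at 37 °C (1044) for temperature, and without wild type replicate 1 (972) or 2 (1005) or knockout replicate 2 (1087) at 30 °C for the knockout. Correlations ran from 0.428 to 0.482 for temperature and from 0.431 to 0.52 for the knockout, with RAD27 and YCL021W-A included. Chromosomes past the threshold stayed at 0 in the camera tests of these fits.

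Deviations of libraries that share a replicate number correlated between groups by -0.111 to 0.114, the highest between the knockout groups at 30 and 37 °C. Such low values do not show whether the numbers pair the samples. A block on replicate number over all groups gave totals of 1925, 3381, 1775, 3409 and 1973, and 17, 18, 14, 15 and 18 lists. A block within genotype gave 2023 genes for temperature in wild type, 3415 in the knockout and 2120 in the interaction. Depth limits the lowest levels, since 3 counts correspond to 0.537 to 0.634 CPM per library before TMM scaling.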

Other observations

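These values were picked after the results were seen and none is explained. HXT4, HXT6 and HXT7, of which HXT6 and HXT7 are near-identical copies, rose in the knockout at 37 °C by 2.05, 3.88 and 3.24 on the log2 scale. The hexose transporter list as a whole did not pass (adjusted p = 0.397, 4 of 7 higher and 2 lower), though it did without knockout replicate 1 at 37 °C (adjusted p = 0.00016). Subunits of RNA polymerases I and III fell in 18 of 20 cases in the knockout at 37 °C (camera adjusted p = 5.32e-05, and adjusted p = 0.455 with an estimated correlation). Spearman's correlation between replicates was lowest for the knockout at 37 °C, 0.9935, and PCK1 stood there at 114.6 ± 94.3 CPM over the 2 libraries.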
